A study of Mus musculus with 12 samples.

How the data were processed

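RNA of 12 arrays was read with Affymetrix Mouse430_2 arrays, per the file headers. Per the labels' protocols, mouse embryonic fibroblasts immortalised with SV40 large T antigen were wildtype or homozygous knockouts of GADD34, and were untreated or received 0.1 mM sodium arsenite for 2 h. Biotin-labelled cRNA was made from total RNA, per the labels' protocols. The design text of the series names 3 replicate experiments with all 4 conditions in each. The deposited values are log2 signal intensities after RMA (background correction, quantile normalisation and summary per probe set), per the submitters' processing notes, which list RMA without its version. The full table held 45101 probe sets. Beside the arrays it gave the authors' log2 group means, their log2 differences and the authors' p-values for 3 comparisons. The test behind those p-values is not given in the sources used here. They equalled a two-sided equal-variance test of unpaired arrays within a tolerance of 1e-06. At the authors' unadjusted p under 0.05 and a change over 0.5, 1712 probe sets passed for arsenite in wildtype cells and 2865 in knockout cells. Between untreated knockout and wildtype cells 5754 passed. With those p-values adjusted by Benjamini-Hochberg and no change threshold, 17, 10 and 2476 probe sets lay under 0.05, in the same order.

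The group of each array was taken from the full table, per the file headers: the array columns name a replicate and an array code, and each of the authors' named mean columns equalled the mean of 1 code's arrays within a tolerance of 1e-06 and of no other. A shorter deposited table held 26382 of the same probe sets, those whose highest group mean was at least 5.64. Its columns carry sample labels, but 10 of 12 hold the values of another array than the full table gives for that label. All 12 follow the column order of the full table. The full table was therefore used, and the fit with the arrays grouped by those labels is given in the closing section.

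Of the probe sets, 64 were controls, 5654 had no gene symbol and 1253 listed several genes. These were left out, so a gene measured only by such probe sets is unmeasured here. Of the 38130 with 1 symbol, 35046 were matched by Entrez identifier to RefSeq (assembly GRCm38.p6, used only for names and for which genes neighbour each other), and 1200 symbols were updated. For the 9634 genes with more than 1 probe set, the one with the highest mean over all arrays was used, which left 20753 genes. No per-array columns were left unused in the full table.

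Groups were compared with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), by 1 fit of the 4 groups to all 12 arrays with 8 residual degrees of freedom and no replicate block, as fixed before the data were examined. Moderated tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each of the 5 comparisons, with a threshold of 0.05. They measure the spread between replicate experiments of these cell populations. Each of 22 gene lists and 10 marker lists was tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry served as alternatives, adjusted over the 32 lists of a comparison. Genes named were Ppp1r15a, up to 10 with the largest rise and up to 10 with the largest fall whose arrays did not overlap, and in each list up to 4 members past the threshold and 2 not past it with the largest changes. The lists and this rule were fixed before the data were examined.

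Whether replicate numbers pair the arrays was checked on array values less their group mean. The 18 pairs with the same number in different groups correlated at 0.231 to 0.738 across genes, and the 36 pairs with different numbers at -0.575 to -0.0106. The counts of genes past the threshold with the number as a block (6 residual degrees of freedom) are therefore given beside those of the fixed fit. The number of arrays limits the precision. Array medians were 5.92 to 5.96. The 3' minus 5' signal of Actb, a measure of RNA integrity, averaged 0.33 and 0.26 in untreated and arsenite-treated wildtype cells and 0.36 and 0.31 in knockout cells.

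The fit was tested on simulated data, with 200 of 20753 genes changed in 10 simulations. For arsenite in wildtype cells it recovered 29.6%, 84.3% and 96.2% of log2 changes of 0.5, 1 and 2. For the difference of responses it recovered 10%, 58.5% and 90% of changes of the same sizes, with 5.40% of the calls false. The simulated noise was independent between arrays, whereas replicate numbers pair the real ones. Fewer genes were changed than were called in the comparisons between groups. These shares may therefore not hold in the data. The alternatives were quantile normalisation again, median centring, the probe sets of the shorter table, leaving out genes dim in all groups (under the 40th percentile), the mean over probe sets, leaving out probe sets that may cross-hybridise, the replicate as a block or random effect, the arrays of the compared groups alone, trended robust variance, array weights, an adjusted p under 0.01, and leaving out each array in turn.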

Results

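Gene expression was measured on 12 Affymetrix Mouse430_2 arrays, which read labelled RNA with sets of short probes. The cells were mouse embryonic fibroblasts made to divide without limit by the SV40 large T antigen. They were wildtype (WT) or carried a knockout (KO) of GADD34, the protein encoded by Ppp1r15a. GADD34 is the stress-induced subunit that brings protein phosphatase 1 to phosphorylated eIF2-alpha and so restores protein synthesis. Cells were untreated or received 0.1 mM sodium arsenite, which binds thiols and causes oxidative stress, for 2 h before lysis. Each of 3 replicate experiments held all 4 conditions, giving 3 arrays per group. Arrays of a group correlated at 0.985 to 0.996 (Pearson's r across 20753 genes, which are not independent replicates). By array, the median correlation with the other arrays of its group was 0.995 in WT and 0.987 to 0.992 in KO cells. KO arrays thus spread more, while the fit gives each gene 1 spread shared by all 4 groups. Changes are log2 differences ± SE (n = 3 arrays per group) from limma's moderated test, with p-values adjusted by Benjamini-Hochberg over all genes tested. Signal under 5.34, the 40th percentile of the array values, may be background, so where the lower group mean lay under it the difference is read as a lower bound. A difference of responses with an untreated mean under it has no exact size. Values are those of each gene's brightest probe set. Of the 146 named values 63 had more than 1 probe set, and in 18 of these another set gave under 50% of the change or the opposite sign (4 values, none over 0.5).

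The signal of Ppp1r15a was lower on every KO array than on every WT array. Its log2 value was 8.45, 8.57 and 8.88 on the untreated WT arrays and 12.24, 12.25 and 11.60 on the arsenite-treated WT arrays. The KO arrays gave 6.42, 6.34 and 6.20 untreated and 6.27, 6.71 and 5.88 under arsenite. The KO minus WT difference was -2.31 ± 0.22 in untreated cells (limma adjusted p = 2.36e-05) and -5.74 ± 0.22 under arsenite (limma adjusted p = 2.34e-08). A single probe set measured the gene. Whether it lies in the deleted part is not given in the sources used here, and a probe set outside it would not check the labels.

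**Figure D1:**
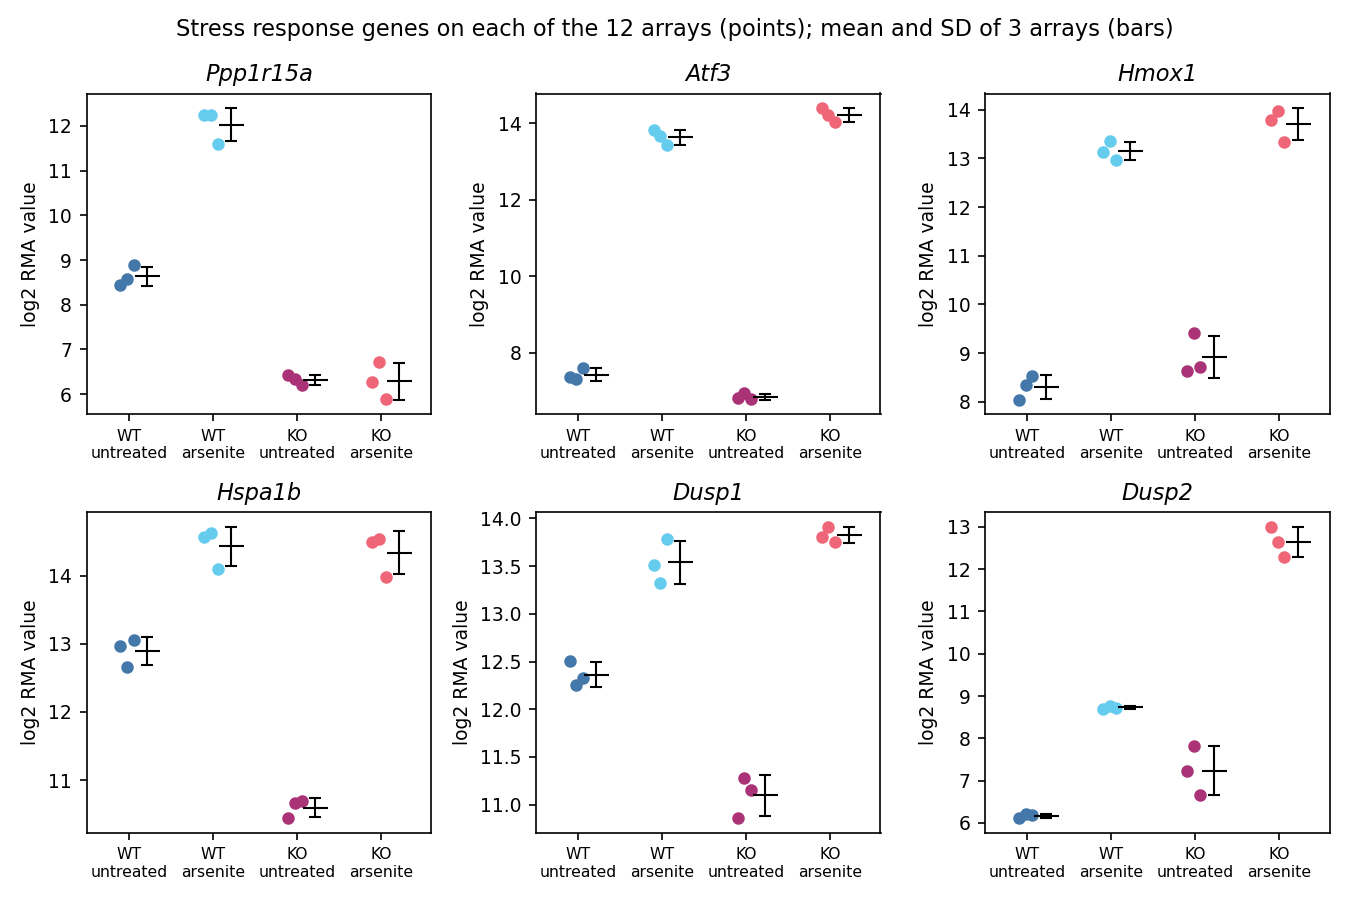
Log2 RMA values of Ppp1r15a, Atf3, Hmox1, Hspa1b, Dusp1 and Dusp2 (y axes, each starting above 0) on the 12 arrays in the 4 groups (x axes). Points are arrays and bars are the mean and SD of 3 arrays. Ppp1r15a averaged 12.03 on arsenite-treated WT arrays and 6.29 on arsenite-treated KO arrays, and Hspa1b averaged 14.43 and 14.34 on the same arrays.

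The first comparison asked which transcripts 2 h of arsenite changed in WT cells. Immediate early transcription factors, which cells switch on within minutes to hours of a stimulus, were among the largest rises. Of the 30 measured, 22 rose and 0 fell, and 27 rose adjusted over the list alone. Egr3 rose by 6.44 ± 0.58, Fosb by 5.90 ± 0.26, Egr2 by 5.55 ± 0.46 and Fos, a subunit of the AP-1 factor, by 5.09 ± 0.45. The untreated means of Egr3 and Fosb lay under 5.34, and the other probe set of Egr3 gave 0.18. Fosl1, another AP-1 subunit, did not pass at 2.22 ± 0.54 (limma adjusted p = 0.0682, and 0.00911 with the replicate block). The list moved up as a set (camera adjusted p = 1.71e-53, and adjusted p = 0.00613 with an estimated correlation). Among 16 MAP kinase phosphatases and Sprouty feedback genes, which damp growth factor signalling, 6 rose and 0 fell, while 10 rose and 1 fell adjusted over the list alone. Errfi1, an inhibitor of the EGF receptor, rose by 3.16 ± 0.40, Dusp2 by 2.56 ± 0.24 and Dusp1 by 1.18 ± 0.14. The camera adjusted p of this list was 9.06e-12, and the adjusted p was 0.0165 with an estimated correlation.

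Transcripts of the integrated stress response rose in the same WT cells. Of 21 measured targets of ATF4 and CHOP, 11 rose and 0 fell, and 14 rose adjusted over the list alone. Atf3, a stress-induced transcription factor that also stands in the immediate early list, rose by 6.21 ± 0.13, and Ppp1r15a by 3.40 ± 0.22. Trib3, a pseudokinase induced by CHOP, rose by 3.21 ± 0.40 and Chac1, which degrades glutathione, by 3.20 ± 0.41. The set shifted up (camera adjusted p = 1.45e-24, and adjusted p = 0.00134 with an estimated correlation). Within the eIF2 list, 2 of 19 members rose and 4 did so adjusted over the list alone. Ppp1r15b, the constitutive partner of the same phosphatase, rose by 0.81 ± 0.10 beside Ppp1r15a, and the list as a whole did not pass (camera adjusted p = 0.320, median -0.05, mean 0.22). Amino acid carriers rose in 3 of 30 listed genes of amino acid supply, and 5 genes rose adjusted over the list alone. Slc3a2 rose by 1.30 ± 0.12 and Slc38a2 by 0.93 ± 0.13. The camera adjusted p of that list was 9.04e-06, against an adjusted p = 0.555 with an estimated correlation.

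Some metal, oxidant and protein-damage genes also rose in WT cells. The metallothioneins Mt2 and Mt1, which bind metals, rose by 3.16 ± 0.28 and 2.14 ± 0.25, and the zinc exporter Slc30a1 by 1.65 ± 0.22. They were 3 of the 6 measured members of the metal response list, where 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000324, and adjusted p = 0.0350 with an estimated correlation). Heme oxygenase Hmox1 rose by 4.85 ± 0.22, the oxidant-induced Osgin1 by 1.24 ± 0.26 and Nfe2l2, which encodes NRF2, by 0.88 ± 0.12. These were 3 of 27 NRF2 targets, also 3 adjusted over the list alone. The median of that list was -0.05, its mean was 0.26, and it did not pass (camera adjusted p = 0.198). Of 23 heat shock chaperones 5 rose, and 9 rose adjusted over the list alone (camera adjusted p = 8.46e-09, but adjusted p = 0.361 with an estimated correlation). The HSP70 genes Hspa1a and Hspa1b rose by 4.20 ± 0.37 and 1.54 ± 0.18, and the co-chaperone Dnajb1 by 2.58 ± 0.27. Because the HSP70 pair is nearly identical in sequence, their probe sets may share signal.

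Further lists moved in part. Of 20 p53 targets 5 rose, and 8 rose adjusted over the list alone. Among them were the antiproliferative Btg2 (3.81 ± 0.30), which also stands in the immediate early list, and the growth arrest gene Gadd45a (2.80 ± 0.33). The activity of p53 itself was not measured. The median of the p53 list was -0.04 and its mean 0.67 (camera adjusted p = 0.000156, adjusted p = 0.361 with an estimated correlation). In the TGF-beta list 4 of 19 rose, and 5 rose and 1 fell adjusted over the list alone, with Skil, a Smad corepressor, at 1.64 ± 0.17 (camera adjusted p = 1.69e-06, adjusted p = 0.0807 with an estimated correlation). Of 21 genes of cholesterol synthesis and uptake 2 rose, or 3 adjusted over the list alone, with Insig1, which holds back sterol-regulated transcription, at 1.57 ± 0.34 (camera adjusted p = 0.00345, adjusted p = 0.759 with an estimated correlation). Among 24 endoplasmic reticulum genes 3 rose, or 4 adjusted over the list alone, led by Herpud1 (2.15 ± 0.28), which helps clear misfolded proteins, and the list did not pass (camera adjusted p = 0.756, median -0.04, mean 0.15). In the list of ubiquitin, proteasome and autophagy genes 4 of 23 rose, or 6 adjusted over the list alone, with the autophagy receptor Sqstm1 at 1.42 ± 0.19 (camera adjusted p = 0.115). Vegfa, a growth factor for blood vessels, rose by 2.66 ± 0.39. Vegfa and Slc2a1 were the 2 of 22 hypoxia genes that rose, while 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.565, median -0.04, mean 0.17).

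Other genes fell in WT cells. Dnm3os, a noncoding RNA that hosts microRNAs, fell by 2.24 ± 0.36. Rpl12, the only one of 25 ribosomal protein genes to pass over all genes or adjusted over the list alone, fell by 1.72 ± 0.31. The ribosomal list shifted down (camera adjusted p = 0.0003, adjusted p = 0.651 with an estimated correlation). Hoxa3 and Hoxd4, which set position along the body axis, fell by 0.98 ± 0.21 and 0.51 ± 0.11. They were 2 of 42 position genes, 3 adjusted over the list alone (camera adjusted p = 0.0605, and 0.0204 with the replicate block). The 4 probe sets of Hoxa3 ran from -1.10 to 0.09. No member passed among 29 NF-kB targets, 30 interferon-stimulated genes, 30 cell cycle genes or 36 matrix genes, over all genes or adjusted over the list alone. None passed among 17 contractile genes, where 1 rose adjusted over the list alone. With the replicate block 2 NF-kB targets and 1 gene each of the interferon-stimulated, cell cycle and contractile lists rose. The NF-kB list then passed with fry (adjusted p = 0.0246) but not with camera (adjusted p = 0.221). In all 441 genes passed in limma, 342 up and 99 down, of which 176 rose and 25 fell at least 2-fold. The count was 1013 with the replicate experiment as a block (641 up and 372 down), 1466 from the 6 WT arrays with that block (819 up and 647 down), 227 at an adjusted p under 0.01, and 255 without WT arsenite replicate 2. It was also moved by leaving out WT arsenite replicate 1 (263) or WT untreated replicate 1 (276) or 2 (269).

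The second comparison asked the same question in KO cells. Immediate early factors again led, with 27 of 30 up and 0 down, also 27 adjusted over the list alone. Fosb rose by 8.10 ± 0.26, Egr2 by 7.15 ± 0.46, Fos by 6.60 ± 0.45 and Atf3 by 7.37 ± 0.13. The set moved up (camera adjusted p = 5.4e-44, and adjusted p = 0.0117 with an estimated correlation). Klf2 and Klf4, transcription factors of the Kruppel family, did not pass at 0.90 ± 0.43 and 0.59 ± 0.35. Of 16 MAP kinase phosphatases and Sprouty genes 7 rose and 2 fell, or 11 and 2 adjusted over the list alone, with Dusp2 at 5.42 ± 0.24 and Dusp1 at 2.73 ± 0.14 (camera adjusted p = 1.46e-07, adjusted p = 0.0648 with an estimated correlation). Of 21 ATF4 and CHOP targets 12 rose and 0 fell, or 13 adjusted over the list alone. Chac1 rose by 4.36 ± 0.41 and Ddit3, which encodes CHOP, by 3.53 ± 0.13, whereas Ppp1r15a itself gave -0.03 ± 0.22 (limma adjusted p = 0.950). This list passed too (camera adjusted p = 2.58e-12, and adjusted p = 0.0117 with an estimated correlation).

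Heat shock chaperones rose in 11 of 23 cases in KO cells, or 16 adjusted over the list alone. Hspa1a rose by 7.15 ± 0.37, Hspa1b by 3.74 ± 0.18, Dnajb1 by 3.39 ± 0.27 and the HSP110 gene Hsph1 by 2.41 ± 0.49. Their camera adjusted p was 1.13e-11, against an adjusted p = 0.314 with an estimated correlation. Mt2 rose by 3.28 ± 0.28 and Mt1 by 1.96 ± 0.25, while the zinc importer Slc39a10 fell by 0.66 ± 0.11. Of the 6 metal genes 3 rose and 1 fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.0395, 0.0912 with the replicate block, and adjusted p = 0.314 with an estimated correlation). Hmox1 rose by 4.78 ± 0.22, 1 of 3 NRF2 targets of 27 that rose, or 4 adjusted over the list alone (camera adjusted p = 0.132). Among 29 NF-kB targets and cytokines 5 rose, or 8 adjusted over the list alone. Ptgs2, an enzyme of prostaglandin synthesis, rose by 2.42 ± 0.53, the cytokine Il6 by 1.90 ± 0.23 and Relb by 1.87 ± 0.25 (camera adjusted p = 0.00221, adjusted p = 0.469 with an estimated correlation). The chemokine Cxcl10 rose by 2.98 ± 0.45 and Ifit2 fell by 0.93 ± 0.25, the only changes in 30 interferon-stimulated genes over all genes or adjusted over the list alone (camera adjusted p = 0.531).

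Smaller parts of other lists rose in KO cells. Of 20 p53 targets 7 rose, or 9 with 1 fall adjusted over the list alone, with Btg2 at 4.53 ± 0.30 and the cell death gene Pmaip1 at 2.80 ± 0.26 (camera adjusted p = 0.0359, 0.0691 with the replicate block, and adjusted p = 0.583 with an estimated correlation). In the TGF-beta list 6 of 19 rose, or 9 with 1 fall adjusted over the list alone, with Hes1, a transcriptional repressor, at 1.53 ± 0.25 (camera adjusted p = 0.00212, adjusted p = 0.314 with an estimated correlation). Cholesterol genes rose in 4 of 21 cases, or 6 adjusted over the list alone, with Insig1 at 1.43 ± 0.34 (camera adjusted p = 0.0104, adjusted p = 0.648 with an estimated correlation). Of 17 contractile genes 2 rose, or 3 adjusted over the list alone, Cnn1, which encodes calponin, by 1.80 ± 0.46 and Fhl2 by 1.31 ± 0.13 (camera adjusted p = 0.00736, adjusted p = 0.469 with an estimated correlation). Of 30 genes of amino acid supply 5 rose, also 5 adjusted over the list alone, with Slc3a2 at 1.01 ± 0.12 (camera adjusted p = 0.0172, adjusted p = 0.633 with an estimated correlation). Of 24 endoplasmic reticulum genes 2 rose and 2 fell, or 3 and 6 adjusted over the list alone. Herpud1 rose by 2.07 ± 0.28 while Edem1, which clears misfolded glycoproteins, fell by 0.65 ± 0.11, and the list did not pass (camera adjusted p = 0.132 down, median -0.14, mean 0.03). The other probe set of Edem1 gave 0.11. The glucose transporter Slc2a1 rose by 1.97 ± 0.11 among 3 rises and 1 fall in 22 hypoxia genes, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.531). No marker list passed with camera under arsenite in either cell type. In KO cells the endothelial and neural lists shifted up with fry (adjusted p = 0.0140 and 0.0342), with 0 of 9 and 0 of 12 members past the threshold, and 1 of 12 muscle markers rose.

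Dnm3os fell by 3.31 ± 0.36 in KO cells and Rpl12 by 2.47 ± 0.31, again the only 1 of 25 ribosomal genes over all genes or adjusted over the list alone (camera adjusted p = 0.00212 down, adjusted p = 0.583 with an estimated correlation). Clec2d, which encodes a C-type lectin, fell by 2.39 ± 0.33, and the kinase gene Taok1 by 1.94 ± 0.31, with the smallest change of its 7 probe sets at -0.08. Among 30 cell cycle genes Ccnb2, a mitotic cyclin, fell by 0.46 ± 0.11, the only one over all genes or adjusted over the list alone (camera adjusted p = 0.0131 down, adjusted p = 0.609 with an estimated correlation). Eif2ak2, the double-stranded RNA kinase of eIF2, fell by 0.73 ± 0.11, and Ppp1r15b rose by 0.68 ± 0.10. They were the 2 of 19 eIF2 list members past the threshold, while 2 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.531). In all 1566 genes passed in limma, 777 up and 789 down, of which 264 rose and 122 fell at least 2-fold. The count was 3051 with the replicate experiment as a block (1376 up and 1675 down), 1551 with quantile normalisation again (860 up and 691 down), 700 at an adjusted p under 0.01, and 937 without KO arsenite replicate 1. With the 6 KO arrays alone it was 476 (309 up and 167 down), against 564 from the 6 WT arrays alone. With the replicate block these became 2917 (1254 up and 1663 down) and 1466. The split into rises and falls and the order depended on the arrays in the fit and on the pairing, and the difference between the counts was not tested.

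Fold changes in both cell types were correlated across the 20753 genes (Pearson's r = 0.780, Spearman's rho = 0.592), which are not independent replicates. Of the 441 genes past the threshold in WT cells, 353 also passed in KO cells, 286 up in both, 67 down in both and 0 in opposite directions. Independent lists of these sizes would share 12.8 rises and 3.76 falls.

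**Figure D2:**
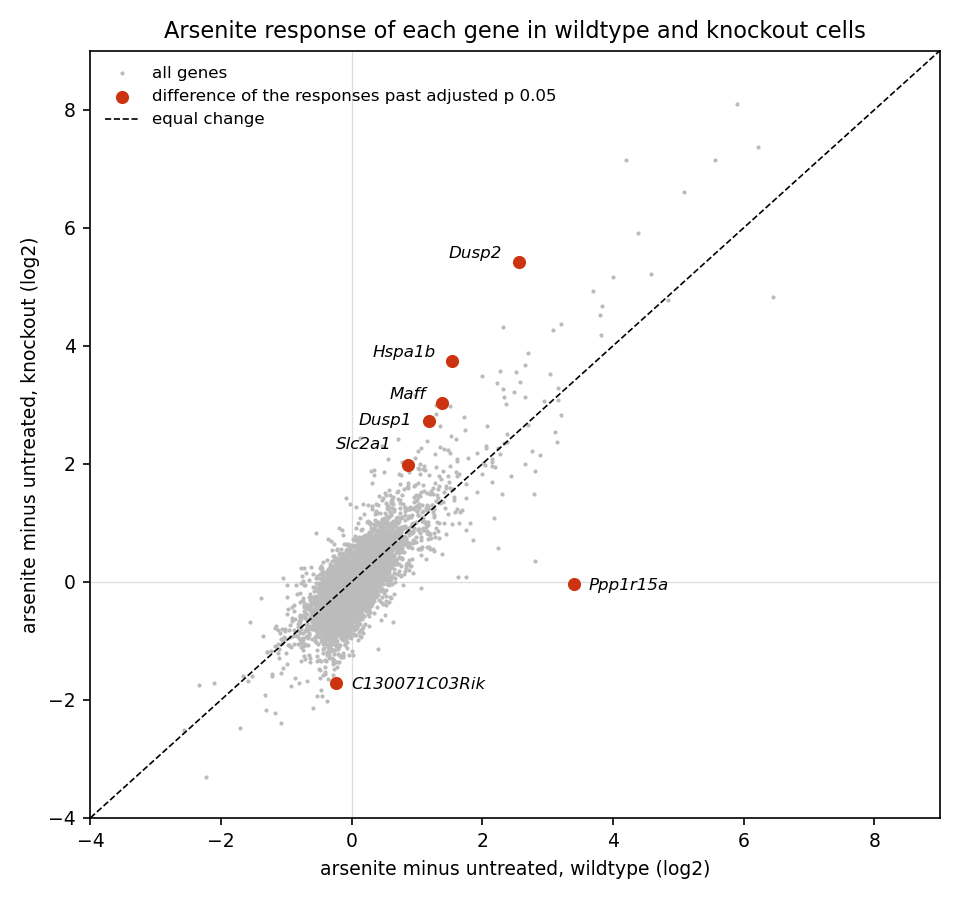
Log2 difference between arsenite-treated and untreated cells in WT (x axis) and KO cells (y axis) for the 20753 genes (grey points). Red points mark the 7 genes whose responses differed at an adjusted p under 0.05, and the dashed line marks equal change. Ppp1r15a rose by 3.40 in WT cells against -0.03 in KO cells, and Dusp2 rose by 2.56 and 5.42.

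The third comparison asked directly whether the arsenite response differed between KO and WT cells. The loss of GADD34 and other differences between these cell populations cannot be told apart by it. The difference of responses passed in limma for 7 genes, 5 larger and 2 lower in KO cells. Dusp2, a nuclear MAP kinase phosphatase, rose by 2.86 ± 0.34 more in KO cells (adjusted p = 0.0254). Hspa1b rose by 2.21 ± 0.26 more (adjusted p = 0.0254), Maff, a small Maf transcription factor, by 1.64 ± 0.22 (adjusted p = 0.0319), Dusp1 by 1.55 ± 0.19 (adjusted p = 0.0266) and Slc2a1 by 1.11 ± 0.15 (adjusted p = 0.0430). The difference was -3.43 ± 0.31 for Ppp1r15a (adjusted p = 0.00400) and -1.47 ± 0.19 for the unnamed transcript C130071C03Rik (adjusted p = 0.0319), whose WT means lay under 5.34 and whose 4 probe sets ran from -1.47 to 0.07. Hspa1b, Maff, Dusp1 and Slc2a1 started lower in untreated KO cells, by -2.30, -1.62, -1.27 and -1.05, and under arsenite the KO minus WT difference was -0.09, 0.02, 0.28 and 0.06. Dusp2 was higher in KO cells by 1.06 ± 0.24 untreated and by 3.92 ± 0.24 under arsenite.

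Among lists, immediate early factors had a median difference of 0.98, with 1 of 30 larger in KO cells over all genes and 10 adjusted over the list alone (camera adjusted p = 2.26e-14, adjusted p = 0.498 with an estimated correlation). Fosb gave 2.20 ± 0.37 (limma adjusted p = 0.106) and Egr3 -1.62 ± 0.82 (limma adjusted p = 0.926), neither of exact size, as untreated means lay under 5.34 for Fosb in both cell types and for Egr3 in WT cells. Of 23 heat shock chaperones 1 differed, or 3 adjusted over the list alone (camera adjusted p = 7.35e-07 up, adjusted p = 0.511 with an estimated correlation), and Hspa1a gave 2.94 ± 0.53 (limma adjusted p = 0.146). NF-kB targets shifted up with 0 of 29 past the threshold and 1 adjusted over the list alone (camera adjusted p = 0.00447, adjusted p = 0.511 with an estimated correlation), and so did contractile genes with 0 of 17 and 1 (camera adjusted p = 0.000515, adjusted p = 0.498 with an estimated correlation). The 48 genes near Ppp1r15a shifted up with 0 past the threshold or adjusted over the list alone (camera adjusted p = 0.0305, adjusted p = 0.498 with an estimated correlation). Endoplasmic reticulum genes (0 of 24) and cell cycle genes (0 of 30) shifted down, each also with 0 adjusted over the list alone. Both had a camera adjusted p of 0.00442, and the adjusted p was 0.498 and 0.742 with an estimated correlation. The eIF2 list shifted down through Ppp1r15a, 1 of 19, or 2 adjusted over the list alone (camera adjusted p = 0.0274, 0.308 with Ppp1r15a left out, 0.106 with the replicate block, and adjusted p = 0.498 with an estimated correlation). ATF4 and CHOP targets did not shift, with Ppp1r15a the only one of 21 past the threshold, while 1 was larger and 2 were lower adjusted over the list alone (camera adjusted p = 0.814). The count of 7 genes became 12 with the replicate block (7 larger and 5 lower in KO cells), 107 on paired differences within experiments (32 larger and 75 lower), 1 at an adjusted p under 0.01 and 4 with probe sets averaged. Leaving out 1 array gave 1 to 69 genes. It was 1 without WT untreated replicate 1 or 3, WT arsenite replicate 1 or 2, or KO untreated replicate 1, and 69 (13 larger and 56 lower) without KO arsenite replicate 3. Ppp1r15a passed in every such fit, and each of the other 6 genes lost its call in at least 1 of them.

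The fourth comparison asked how untreated KO cells differed from untreated WT cells. Over all 20753 genes 20.1% passed, so a list with about that share past the threshold does not stand out by its count. Igfbp2, which binds insulin-like growth factors, was higher in KO cells by 9.25 ± 0.41, and Zic1, a transcription factor of neural and somite development, by 8.97 ± 0.18. The imprinted noncoding RNA Rian was higher by 7.86 ± 0.23, the imprinted Mest by 6.43 ± 0.66, and Sim2, another developmental transcription factor, by 6.77 ± 0.14. Cd34, a surface marker of fibroblast and vascular progenitors, was lower by -6.93 ± 0.42, Mbnl3, a splicing regulator, by -7.33 ± 0.19, and the purinergic receptor P2ry14 by -6.88 ± 0.19. Of these, all but Cd34 had a lower group mean under 5.34, so their sizes are lower bounds and are not ranked. Another probe set gave 1.49 for Sim2 and 1.59 for Rian. Of 42 Hox and position genes 11 were higher and 9 lower, the same adjusted over the list alone, including Hoxd8 (-4.59 ± 0.12), Hoxb6 (-4.49 ± 0.19) and Hoxb5 (-4.46 ± 0.26), with the KO means of Hoxd8 and Hoxb5 under 5.34. The members went both ways, and the list did not shift against other genes (camera adjusted p = 0.927, with a median of 0.04 and a mean of -0.16). Fry, which tests the list alone, passed (fry adjusted p = 0.00369, and 0.00309 with the replicate block). Xist, the RNA that coats the inactive X chromosome of female cells, was higher by 7.12 ± 0.18, at 12.58 ± 0.09 (SD) on untreated KO arrays and 5.46 ± 0.42 (SD) on untreated WT arrays. Of 5 sex chromosome genes 1 was higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.785, but fry adjusted p = 3.36e-05). The group means of the 4 Y-linked genes were 3.18 to 4.22, all under 5.34, so the lower call is not read as a difference.

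**Figure D3:**
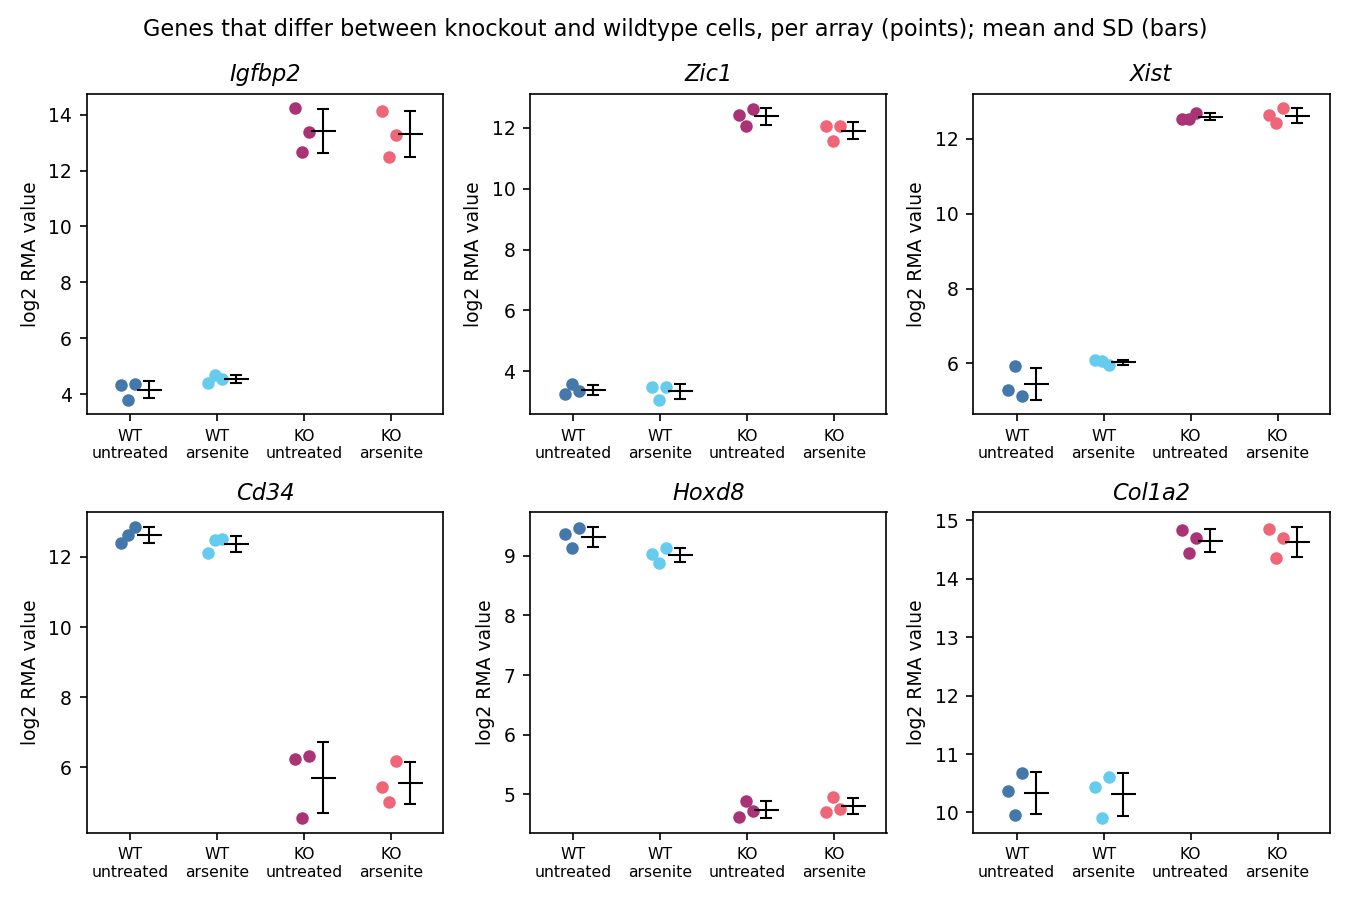
Log2 RMA values of Igfbp2, Zic1, Xist, Cd34, Hoxd8 and Col1a2 (y axes, each starting above 0) on the 12 arrays in the 4 groups (x axes). Points are arrays and bars are the mean and SD of 3 arrays. Zic1 averaged 3.40 on untreated WT and 12.37 on untreated KO arrays, and Cd34 averaged 12.63 and 5.70.

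Of 21 ATF4 and CHOP targets 0 were higher and 10 lower in untreated KO cells, or 1 and 10 adjusted over the list alone, and Ppp1r15a was 1 of the 10. Chac1 was at -1.57 ± 0.41, Ddit3 at -1.33 ± 0.13 and Ddit4, an inhibitor of mTOR signalling, at -1.24 ± 0.25 (camera adjusted p = 0.0122, 0.0342 with Ppp1r15a left out, and adjusted p = 0.691 with an estimated correlation). Of 17 contractile genes 9 were lower and 0 higher, or 11 and 1 adjusted over the list alone, with Cnn1 at -4.30 ± 0.46 and smooth muscle actin Actg2 at -3.71 ± 0.39 (camera adjusted p = 0.000938, adjusted p = 0.691 with an estimated correlation). Ribosomal protein genes were higher in 6 of 25 cases, the same adjusted over the list alone, with Rps24 at 0.54 ± 0.09 (camera adjusted p = 0.0122, adjusted p = 0.929 with an estimated correlation). Of 23 heat shock chaperones 2 were higher and 6 lower, or 2 and 7 adjusted over the list alone. Hspa1a was at -3.25 ± 0.37 and Hspa1b at -2.30 ± 0.18, but the small heat shock gene Cryab at 2.16 ± 0.29 (camera adjusted p = 0.400, median 0.01, mean -0.37). The 3 probe sets of Cryab ran from 0.07 to 2.85. Immediate early genes were lower in 6 and higher in 1 of 30 cases, or 9 and 1 adjusted over the list alone, with Maff at -1.62 ± 0.15 and Egr3, whose WT mean lay under 5.34, at 3.51 ± 0.58 (camera adjusted p = 0.0708). NF-kB targets were lower in 10 and higher in 2 of 29 cases, or 11 and 3 adjusted over the list alone, with the chemokine Ccl2 at -2.88 ± 0.47 and Il6, whose WT mean lay under 5.34, at 1.98 ± 0.23 (camera adjusted p = 0.104). Hypoxia genes were lower in 8 and higher in 1 of 22 cases, or 8 and 2 adjusted over the list alone, with the hexokinase Hk2 at 1.60 ± 0.22 and Slc2a1 at -1.05 ± 0.11 (camera adjusted p = 0.0713, but fry adjusted p = 0.0194).

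Matrix and marker genes went both ways in untreated cells. Of 36 matrix genes 8 were higher and 5 lower, or 8 and 6 adjusted over the list alone. The collagen gene Col1a2 was at 4.32 ± 0.22 and Loxl2, which crosslinks collagen, at -3.24 ± 0.41 (camera adjusted p = 0.655). General fibroblast markers were lower in 4 of 11 cases, the same adjusted over the list alone, among them Thy1 at -2.18 ± 0.10 and podoplanin, Pdpn, at -2.72 ± 0.14 (camera adjusted p = 0.0708, but fry adjusted p = 2.97e-05, and 4.33e-06 with the replicate block). Of 11 cartilage and bone markers 3 were higher and 1 lower, or 3 and 2 adjusted over the list alone, with Col2a1 at 2.72 ± 0.30 (camera adjusted p = 0.446). Of 9 adipocyte markers 1 was lower, also 1 adjusted over the list alone, lipoprotein lipase Lpl at -3.61 ± 0.55 with a KO mean under 5.34 (camera adjusted p = 0.446). Endothelial (1 lower of 9), blood cell (2 lower of 11), epithelial (2 higher and 1 lower of 12), neural (2 higher and 1 lower of 12) and muscle markers (1 lower of 12) did not shift against other genes by camera, and adjusted over the list alone the counts were the same except for 2 neural markers lower. Their camera adjusted p was 0.356, 0.655, 0.811, 0.927 and 0.680. The fry adjusted p was 0.00322 for the endothelial list, which passed, and at least 0.327 for the others, and none of the 8 germ cell markers passed. Of 48 genes near Ppp1r15a 9 were higher and 2 lower, the same adjusted over the list alone, with Bcat2, an enzyme of branched-chain amino acid breakdown, at 2.46 ± 0.18 and Nucb1 at -1.78 ± 0.20 (camera adjusted p = 0.356, but fry adjusted p = 0.0342). In all 4181 genes passed in limma, 2041 higher and 2140 lower in KO cells, of which 636 and 633 differed at least 2-fold. The count was 6052 with the replicate block (2962 higher and 3090 lower) and 2485 at an adjusted p under 0.01. The labels name no second line of either genotype, so the comparison is between these cell populations.

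The fifth comparison set KO against WT cells under arsenite. Here 21.1% of all genes passed, the share against which the list counts are to be read. Igfbp2 was higher by 8.76 ± 0.41, Zic1 by 8.54 ± 0.18 and Sim2 by 6.87 ± 0.14, and Cd34 was lower by -6.82 ± 0.42, close to the untreated differences. The WT means of Igfbp2, Zic1 and Sim2 again lay under 5.34. Of 42 Hox and position genes 11 were higher and 10 lower, the same adjusted over the list alone, with Hoxd8 at -4.22 ± 0.12 (camera adjusted p = 0.871, but fry adjusted p = 0.0137). ATF4 and CHOP targets were lower in 8 and higher in 1 of 21 cases, the same adjusted over the list alone, with Trib3 at -1.33 ± 0.40 and Ddit4 at -1.66 ± 0.25 beside Ppp1r15a (camera adjusted p = 0.0205, and adjusted p = 0.452 with an estimated correlation). With Ppp1r15a left out of the test this list no longer passed with camera (adjusted p = 0.0578) but did with fry (adjusted p = 0.0202), with 7 lower and 1 higher of 20. Immediate early factors were higher in 8 of 30 cases and lower in 0, or 12 and 0 adjusted over the list alone. Fosb was at 1.89 ± 0.26 and Zfp36, an RNA-destabilising protein, at 1.24 ± 0.29 (camera adjusted p = 0.0363, 0.0673 with the replicate block, and adjusted p = 0.905 with an estimated correlation). Il6 was higher by 3.54 ± 0.23 and Ccl2 lower by -2.30 ± 0.47, in an NF-kB list with 3 higher and 7 lower of 29, or 4 and 7 adjusted over the list alone (camera adjusted p = 0.831, median 0.07, mean -0.07).

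Cell cycle genes were lower under arsenite in KO cells in 7 of 30 cases, the same adjusted over the list alone. Ccne2, a cyclin of S phase entry, was at -0.98 ± 0.25 and thymidylate synthase, Tyms, at -0.58 ± 0.16 (camera adjusted p = 0.0329, adjusted p = 0.905 with an estimated correlation). The smallest change of the 4 probe sets of Tyms was -0.06. Ribosomal protein genes were higher in 5 of 25 cases, the same adjusted over the list alone (camera adjusted p = 0.0456, 0.0856 with the replicate block, and adjusted p = 0.905 with an estimated correlation). Genes near Ppp1r15a were higher in 13 and lower in 1 of 48 cases, the same adjusted over the list alone, with Bcat2 at 2.04 ± 0.18 (camera adjusted p = 0.0205, adjusted p = 0.452 with an estimated correlation). Fibroblast markers were lower in 5 of 11 cases, the same adjusted over the list alone, with Thy1 at -1.66 ± 0.10 (camera adjusted p = 0.0205, adjusted p = 0.452 with an estimated correlation). In all 4370 genes passed in limma, 2130 higher and 2240 lower, of which 591 and 700 differed at least 2-fold. The count was 6264 with the replicate block (3141 higher and 3123 lower) and 2617 at an adjusted p under 0.01. KO minus WT differences without and with arsenite were correlated across genes (Pearson's r = 0.924), and 3153 genes passed in both, 1537 higher, 1613 lower and 3 in opposite directions. Independent lists of these sizes would share 209 and 231.

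**Figure D4:**
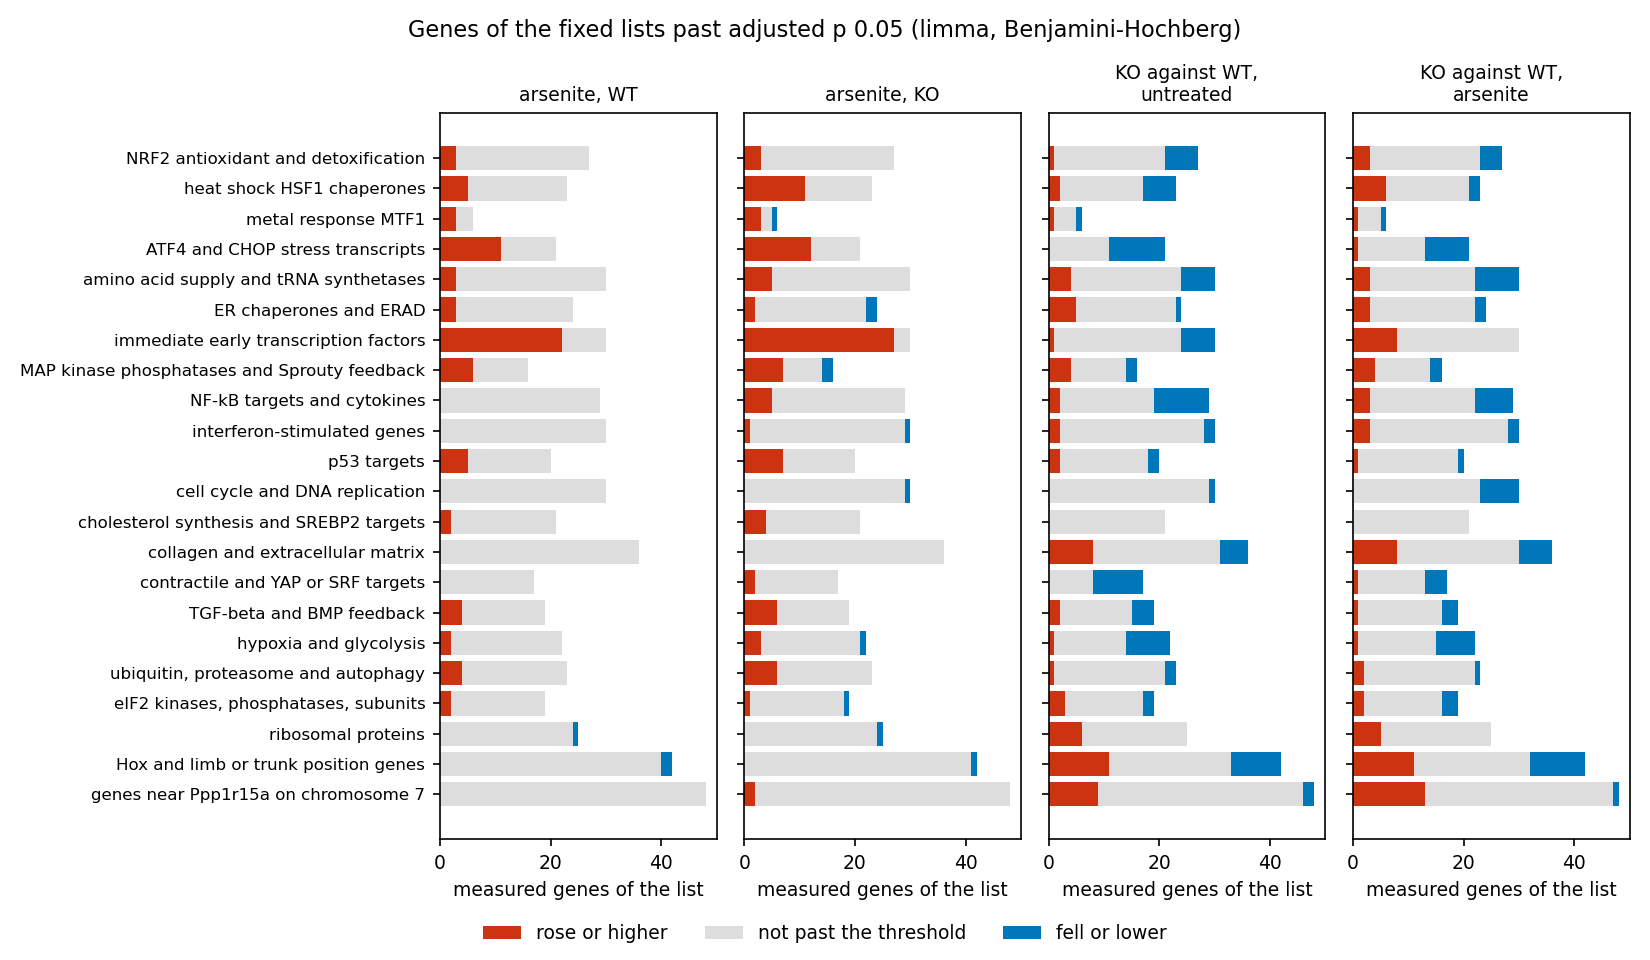
Number of measured genes (x axes) of each of the 22 fixed lists (y axis) that were higher, lower or not past an adjusted p of 0.05 in the 4 comparisons between groups. Immediate early factors rose in 22 of 30 cases in WT cells and 27 of 30 in KO cells, and Hox and position genes were split, with 11 higher and 9 lower in untreated KO cells.

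Of the camera calls above, those for immediate early factors and for ATF4 and CHOP targets held with an estimated correlation under arsenite in both cell types. Those for the metal response and for MAP kinase phosphatases held in WT cells only, and none of the other camera calls held.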

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

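The splits, the test of segments as the whole difference, the tests of single experiments and the ceiling test of the immediate early list were set before their results were seen, and the other tests of these patterns were chosen only after them. For each comparison, the 6 arrays (for the difference of responses, the 6 arsenite minus untreated differences) make 10 splits, too few for a share under 0.1. The real split was the 1 that called genes: 564 for arsenite in wildtype cells, 476 in knockout cells, 3853 between genotypes untreated, 3537 under arsenite and 107 for the difference of responses. As the numbers pair the samples, each real split compares with the 3 others that part all 3 pairs, where the highest count was 0, and the other 6 part 1 pair and also gave 0. Every split but the real one mixes the compared groups, so a real difference widens its spread. The counts of 0 therefore do not show what chance alone would give.

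The arsenite response differed between genotypes, by the test of the difference, for Ppp1r15a (-3.43), which did not respond in knockout cells, and for C130071C03Rik (-1.47, and up to 0.07 on its 3 other probe sets), a transcript that fell in knockout cells and lay under the 40th percentile of array values (5.34) in wildtype cells, where a fall could not be seen.

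Hspa1b (2.21), Maff (1.64), Dusp1 (1.55), Slc2a1 (1.11) and Dusp2 (2.86) rose more in knockout cells by the same test. No single replicate experiment made the first 4 differences, which kept at least 87.5% of their size without any 1 experiment. In wildtype cells under arsenite, Maff and Slc2a1 lay below the 99th percentile of array values (highest mean 12.75 against 13.4). These 4 started lower in untreated knockout cells, and their knockout minus wildtype difference under arsenite was at most 18.3% of the difference of responses. That share restates the difference of responses, so it does not test a lower starting level, which stays open. A signal ceiling cannot be told apart for any of the 4, since a single probe set may level off below that percentile. The wildtype arsenite means of Hspa1b and Dusp1 lay above it, at 14.43 and 13.54. Neither a lower start nor a ceiling covers Dusp2, which was 3.92 higher in knockout cells under arsenite. Its probe set read 8.73 in wildtype cells under arsenite and 12.65 in knockout cells. The loss of GADD34 and other differences between the cell populations stay open for all 5 genes.

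The immediate early list had a median difference of responses of 0.98 and a mean of 0.83. The median stayed at 0.581 or above without any 1 replicate experiment, with 0.581 without experiment 1, 1.11 without experiment 2 and 1.12 without experiment 3. No single experiment made all of it, but experiment 1 made it larger. A lower starting level alone, with an equal level reached under arsenite, would leave no difference there. Under arsenite the list mean was 0.488 ± 0.147 (SE) higher in knockout cells, with the lowest knockout array at 12.51 and the highest wildtype array at 12.27. The list's camera call under arsenite did not hold with the replicate block or an estimated correlation. The list mean therefore argues only weakly against a lower start as the whole difference of responses. A lower start as part of it cannot be told apart, as the untreated list mean was -0.339 ± 0.260 (SE) against wildtype cells, nor can a signal ceiling in the wildtype arrays, since 20% of the list (6 of 30) lay above the 99th percentile there. The loss of GADD34 stays open beside differences between the cell populations.

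Knockout and wildtype cells differed in 4181 genes untreated. Medians over windows of 51 neighbouring genes had an SD of 0.216, against at most 0.0661 in 100 shuffles. Arsenite within knockout cells, where both groups are the same cell population, also exceeded its shuffles, at 0.0699 against at most 0.0530. In wildtype cells arsenite gave 0.03684 against at most 0.03675. An excess thus also arises without a difference in segments. Gained or lost chromosome segments may be part of the difference, but the excess alone does not show them. The chromosome with the highest median (0.55) had 204 genes higher and 17 lower of 391. The one with the lowest (-0.37) had 21 higher and 232 lower of 573. Segments longer than the window that shift all their genes alike would leave little once the neighbourhood median is taken off. Among 11878 expressed genes with a known neighbourhood, 3978 passed the threshold before it was taken off and 3269 after. Of the 3978, 64.4% (2563) stayed past the threshold in the same direction. This argues against long and even segments as the whole difference. Shorter or uneven segments are not removed by the neighbourhood median, so the test cannot decide on those. For these genes as a whole, separate cell populations and the loss of GADD34 cannot be told apart, because the design holds them together. Of 42 Hox and position genes, 20 differed in the same direction in both conditions. Xist, the RNA of the inactive X chromosome, averaged 12.58 and 12.61 in knockout cells untreated and under arsenite, against 5.46 and 6.04 in wildtype cells. The populations thus also differed in a sex-linked transcript, and the labels do not give the sex of the embryos.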

How the results depend on the processing

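The alternatives were chosen before the data were examined, except the grouping by sample labels, the equal-variance test, the compared groups' arrays with the replicate block, the paired differences and the lists without Ppp1r15a, and the test of column order was also chosen after its result was seen. Genes past the threshold numbered 441 for arsenite in wildtype cells, 1566 in knockout cells, 4181 and 4370 between genotypes untreated and under arsenite, and 7 for the difference of responses. Of the planned settings, 8 of 12, 8 of 12, 11 of 12, 11 of 12 and 6 of 11 stayed within 1.5 times. In the same order, the replicate block gave 1013, 3051, 6052, 6264 and 12 genes (every gene of the fixed fit was also called), the random effect 860, 2723 and 19, array weights 711 and 12 (first and last), the mean over probe sets 4 (last) and an adjusted p under 0.01 gave 227, 700, 2485, 2617 and 1, by its construction. The equal-variance test gave 39, 21, 1806 and 1434, and was not run for the last. With the compared groups' arrays alone, arsenite in knockout cells gave 476, and with the replicate block 1466 in wildtype and 2917 in knockout cells; paired differences gave 107 for the last. The cause of the other shifts was not tested. Leaving out 1 array gave 255 to 493 (over 1.5 times lower without wildtype untreated 1 or 2 or wildtype arsenite 1 or 2), 937 to 1809 (lower without knockout arsenite 1), 3206 to 4422, 3350 to 4520, and 1 to 69 (outside 1.5 times for all but knockout untreated 2). With arrays grouped by the shorter table's sample labels, limma gave 0 genes in all 5 comparisons, with 22, 17, 30, 25 and 33 at an unadjusted p under 0.05 and no other tool run; the full table's groups gave 4262 between untreated genotypes on the same probe sets, which argues against wrong group means, and 12 of 12 columns followed the full table's order, so the labels are likely displaced. Lists past the threshold numbered 10, 13, 3, 6 and 8 with camera, and 4, 2, 0, 0 and 0 with an estimated correlation. Fry gave 5 for arsenite in wildtype cells, 10 between untreated genotypes and 0 for the difference of responses. Fry with the replicate block gave 21, 16, 12 and 3, in that order for all but arsenite in wildtype cells. The mean over probe sets gave 5 between untreated genotypes and leaving out dim genes 2 between genotypes under arsenite. Leaving out 1 array gave 9 to 12, 7 to 16 (lower without knockout arsenite 3), 2 to 5 (higher without wildtype untreated 3), 4 to 6 and 6 to 9 lists. With camera the replicate block ended the calls of metal and p53 lists in knockout cells, immediate early and ribosomal lists under arsenite and the eIF2 list for the difference of responses, and added Hox genes in wildtype cells. Without Ppp1r15a the lists past the threshold with camera numbered 10, 13, 3, 4 and 7. The camera calls of ATF4 and ribosomal lists under arsenite and the eIF2 list for the difference of responses ended. All 40 list calls kept their direction under quantile normalisation again and median centring, and 36 and 39 kept their call. Of 146 named gene values, 142 never reversed and 114 kept direction and call in all 24 settings. The values that reversed, none past the threshold in either direction, did so only where 1 array was left out. Between genotypes under arsenite they were Hspa1b (-0.26 to 0.086, above 0 at 0.0069 without wildtype arsenite 2 and 0.086 without knockout arsenite 3), Maff (-0.010 to 0.062, below 0 at -0.0082 without wildtype arsenite 2 and -0.010 without knockout arsenite 1) and Slc2a1 (-0.018 to 0.14, below 0 without knockout arsenite 2). By arsenite in knockout cells it was Ppp1r15a (-0.25 to 0.17, above 0 at 0.017 without knockout untreated 1 and 0.17 without knockout arsenite 3). Among named genes, the replicate block changed the call of Fosl1 alone. Values of the other table were identical, so its probe sets were run instead.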

Other observations

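The tests of zinc-finger genes were set before their results were seen, on a group of genes noticed in the data, and the imprinted and zinc-finger genes named here were chosen after their values were seen. Of 343 measured genes whose symbol is Zfp and a number, 107 were higher and 13 lower in untreated knockout cells (116 and 24 under arsenite), while arsenite raised 20 and lowered 9 in wildtype cells and raised 30 and lowered 29 in knockout cells. Zfp618 was higher by 3.76 ± 0.21 and Zfp521 lower by -2.69 ± 0.52. Expression level does not account for the shift, since the highest median of 10000 lists matched on it was 0.0598 against 0.22. The median over 272 of these genes was 0.24 before and 0.203 after the neighbourhood median was taken off. This argues against long and even chromosome segments as the whole shift. The neighbourhood median does not remove shorter or uneven segments, so the test cannot decide on those. As the group was noticed in these same data, neither check shows how far its shift exceeds chance.

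Of 32 imprinted genes, 12 were higher and 3 lower in untreated knockout cells, and 11 and 3 under arsenite. Rian was higher by 7.86, Mest by 6.43, Meg3 by 5.49 and Dlk1 by 3.57, and Cdkn1c was lower by -2.21 and Igf2r by -1.01.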
